A study of Homo sapiens with 6 samples.

How the data were processed

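RNA was studied in 6 libraries of EndoC-βH1, a human pancreatic beta cell line, carrying a lentiviral construct for a short hairpin RNA (shRNA) whose production is switched on by doxycycline. In 3 libraries the shRNA, aimed at the insulin gene (INS) promoter, was induced by 7 days in doxycycline at 1 mg/mL, and in 3 negative control libraries no doxycycline was added. Per the labels' protocols, total RNA was extracted, and full-length cDNA was made from 10 ng of RNA with a template-switching low-input kit and cut into libraries with a transposase-based kit. Groups and replicate numbers were taken from the sample titles.

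The file analysed was 1 merged transcript assembly for the whole series. Its source column reads Cufflinks, and its tags are those that Cuffmerge and Cuffcompare write, per the tags in the deposited file. TopHat2, Cufflinks and hg19 are named in the submitters' processing notes, without versions. Alignment settings, assembly settings and filters are not given in the sources used here. The deposited values are exon start and end positions in bases, counted from 1, and text tags for the gene name, the locus, the nearest RefSeq transcript and the relation to it. All 555595 lines are exons, and 0 of them has a number in the score column. The file therefore gives no abundance per library or per group. Sequencing depth is unknown, and no expression test, fold change or replicate spread could be computed. The planned expression tests, which assumed FPKM values, were replaced by a description of the transcript models. Expression values of the 6 libraries were not analysed here.

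Models were rebuilt from the exon lines in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pysam 0.24.0. A model was called a reference transcript when its class was an exact match and its original name a RefSeq accession. A model of class j, which shares splice junctions with a reference transcript but not its whole intron chain, was called a joined model. An intron was called annotated when its start, end and strand were those of an intron of a reference transcript in the file. For each joined model, the fewest consecutive runs of introns, each from 1 reference transcript of the same locus, that make up its chain were counted. The build was checked on the GRCh37 sequence: 98.6% of the 219168 distinct reference introns that could be read began with GT and ended with AG, and a further 0.983% were GC-AG. Intron chains were compared with GENCODE release 44 mapped to GRCh37, requiring every intron to be identical. For joined models with a protein-coding nearest reference, the longest reading frame from ATG to a stop was found on the spliced genome sequence of both. The frames of single named models were also read where the nearest reference has a non-coding accession. A stop was called early when it lay more than 50 bases before the last junction.

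The share of genes with a joined model was taken over gene names with a reference transcript of at least 2 exons, with exact Clopper-Pearson 95% intervals, which cover counting error only. The 13 gene lists were fixed before the data were examined. Each was compared with 10000 random lists of equal size, drawn from genes in the same deciles of reference transcript number and exon number, with a two-sided empirical p and Benjamini-Hochberg adjustment over the 13 lists. The test was checked on simulated calls over 21516 genes. Of 200 simulated lists of 20 genes with no effect, 2% had an unadjusted p under 0.05. At the same unadjusted threshold, 38.5% and 91% were recovered when the odds of a joined model were raised by a factor of 3 and 8. Calls were simulated from the rates of the same deciles used for matching. The check therefore cannot show whether that matching suffices in the real data.

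Named genes followed a rule fixed beforehand: INS and its listed neighbours, the 3 members of each other list with the most joined models, and the 10 genes of the whole file with the most. One gene that the rule names is not reported here. For the neighbours, positions and counts are given for those with a joined model and names for the rest. Alternatives were a restriction to chromosomes 1 to 22, X and Y, minimum model sizes, counting by locus, other matching and a stricter call. The planned tests on antisense models and on intergenic loci near INS had no members to test.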

Results

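The series was designed to compare the transcriptome of EndoC-βH1 beta cells with the INS-promoter shRNA induced against cells carrying the same construct without doxycycline, with 3 libraries in each group. INS encodes insulin. The data examined here were the merged transcript models of the whole series, which carry no abundance, so the level of INS in each library, the check of the knockdown and the difference between the groups were not analysed here. Doxycycline was present in the induced group alone, and the labels list no doxycycline-treated group without the hairpin. The results below describe which transcripts of the insulin locus, of beta cell genes and of the rest of the genome the assembly contained. Nothing in them has a replicate or a direction between the groups.

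The assembly held 55083 transcript models at 26008 loci with 25211 gene names. Of these, 49846 matched a RefSeq transcript and 5237 (9.51%) were joined models with an intron chain absent from RefSeq, spread over 2677 gene names. The assembly listed 0 antisense, 0 intronic and 0 intergenic models. Since the filters applied are unknown, these zeros do not show that the cells lacked such transcripts. The reference part was carried over whether or not a gene belongs to beta cells, since 394 olfactory receptor gene names were among it. A reference model in the file is therefore no measure of expression.

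The insulin gene lay in 1 locus with its neighbour IGF2, which encodes a growth factor, and with INS-IGF2, the read-through transcript of both. On hg19 the locus spanned chromosome 11 from 2150342 to 2182439 on the minus strand. INS itself (2181009 to 2182439) had 4 RefSeq transcripts of 465 to 644 spliced bases and no joined model. All 4 contained the same longest reading frame of 110 amino acids and differed only in the 5′ part, where the first exon measured 42, 68 or 102 bases or was fused with the next exon into 1 exon of 425 bases. IGF2 (2150347 to 2170833) had 5 RefSeq transcripts and no joined model. INS-IGF2 had 2 RefSeq transcripts and 2 joined models.

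Both joined models at INS-IGF2 attached an annotated alternative first exon of INS to an annotated INS-IGF2 chain. The longer model had 7 exons and 5158 spliced bases, ran to the IGF2 3′ end and began with the 68-base first exon. The shorter had 5 exons and 891 spliced bases and began with the 102-base first exon. The longest frame was 200 amino acids in both and in the reference tagged as nearest to both, a RefSeq transcript with a non-coding accession. Apart from its first exon, the shorter model had the exons of the INS-IGF2 RefSeq transcript with a protein-coding accession. That transcript had 831 spliced bases and a longest frame of 200 amino acids. In the longer model, and in its nearest reference, the stop lay more than 50 bases before the last junction. Neither chain was present in GENCODE, whereas those of 10 of the 11 RefSeq transcripts at the locus were. The exception was the INS transcript with the 102-base first exon, which the shorter joined model also used. The 4 INS and 4 INS-IGF2 models shared 1 start site group, so a value summed per start site or per locus in this assembly would add INS and INS-IGF2 together, and at the locus level IGF2 as well. Across the file, 616 loci (2.37%) and 431 start site groups held more than 1 gene name.

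**Figure D1:**
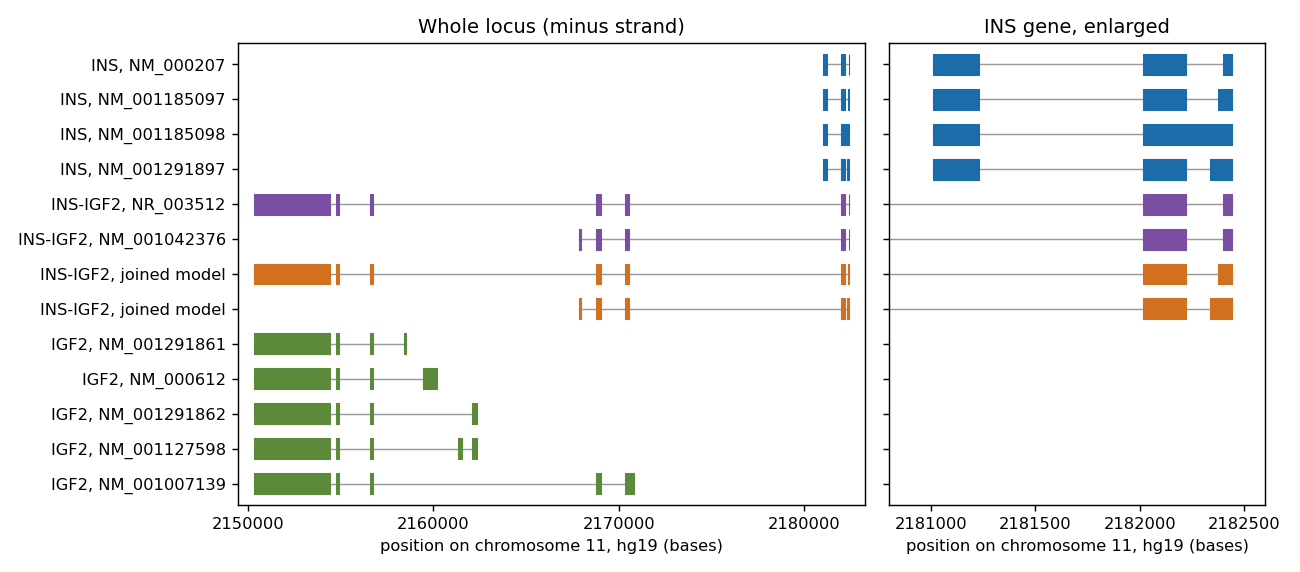
Exons (boxes) and introns (lines) of the 13 models at the insulin locus against position on chromosome 11 (hg19, bases), for the whole locus and enlarged at INS; blue, purple and green are RefSeq transcripts of INS, INS-IGF2 and IGF2, and orange marks the joined models. The 2 joined models use the 68-base and 102-base first exons of INS and the exons of INS-IGF2.

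Few of the 32 listed genes around INS on chromosome 11 had a joined model, and 16 of them had a single RefSeq transcript. Besides INS-IGF2, joined models occurred at TNNT3 (1940799 to 1959936), a troponin T of fast skeletal muscle, with 2, at BRSK2 (1411129 to 1483919), a protein kinase, with 1, and at CARS (3022152 to 3078681), a cysteinyl-tRNA synthetase, with 1. None was present at TH, the tyrosine hydroxylase gene whose nearest edge lay 2720 bases from the INS start, at SYT8, a synaptotagmin 323688 bases away, or at KCNQ1, a potassium channel 283782 bases away. The other listed neighbours, IGF2-AS, ASCL2, H19, MRPL23, LSP1, TNNI2, CTSD, DUSP8, MOB2, C11orf21, TSPAN32, CD81, TSSC4, TRPM5, KCNQ1OT1, CDKN1C, SLC22A18, PHLDA2, NAP1L4, TOLLIP, IFITM10, FAM99A and KRTAP5-1, had none either. Of the 30 members with a multi-exon reference transcript, 4 (13.3%, 95% interval 3.76 to 30.7%) had a joined model, against 16.3% in matched random lists (adjusted p = 1, permutation test on random lists). The direction turned with the comparison, since the random share was 10.7% with matching on genomic span and 12.5% without matching.

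In the secretory granule list, 5 of 21 genes had one (23.8%, matched 20.5%): PAM, which amidates peptide hormones, and SLC30A8, the zinc transporter of insulin granules, had 3 each, and PTPRN, a granule membrane protein, PTPRN2 and RAB27A had 1 each. In the exocytosis and excitability list, 8 of 28 genes had one (28.6%, matched 25.7%), led by the calcium channel gene CACNA1C with 8, the potassium channel gene KCNMA1 with 4 and, with 2 each, the calcium channel subunit gene CACNB2, RIMS2 and TRPM3. In the list of beta cell transcription factors, 3 of 22 had one (13.6%, matched 15.9%): TCF7L2 had 4, and PAX6 and RFX3 had 1 each. Without matching, the random share was 12.5%, below that of the list. In the glucose sensing and incretin list, 2 of 21 had one (9.52%, matched 14.8%), LDHA, a lactate dehydrogenase, with 2, and PDHA1, a pyruvate dehydrogenase subunit, with 1. Genes at diabetes susceptibility loci had one in 10 of 39 cases (25.6%, matched 18.5%), including TCF7L2 with 4, and ANK1, IGF2BP2 and SLC30A8 with 3 each. Matching on genomic span in place of transcript number lowered the matched share to 14.1% for granule genes and 19.4% for exocytosis and excitability genes, and without matching that of diabetes loci was 12.4%; none of the 3 lists passed the threshold in the permutation test under these settings.

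Of the models at these genes, the chain of 1 of the 4 at KCNMA1 and the single ones at PAX6, a regulator of islet development, and RAB27A were present in GENCODE, and none of those at PAM, SLC30A8, PTPRN, PTPRN2, TCF7L2, RFX3, CACNA1C, CACNB2, RIMS2, TRPM3, LDHA, PDHA1, ANK1 or IGF2BP2 was. The longest frames of the 3 SLC30A8 models were 320, 320 and 369 amino acids, against 320 in the nearest reference. Those of the 3 PAM models were 683, 808 and 877 amino acids, against 974. Those of the 2 LDHA models were 101 and 270, against 361. Those of the 4 TCF7L2 models were 447, 545, 607 and 643, against 476, so that 3 were longer than in that reference. SLC30A8 had 5 RefSeq transcripts, PAM and LDHA 6 each and TCF7L2 13. Only the transcript tagged as nearest was compared, and it was the same for all joined models of each of these genes. A frame called longer or shorter here may be that of another RefSeq transcript.

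The ER stress list had 2 of 25 (8%, matched 10.6%), ATF3 and HERPUD1, with 1 model each. Other islet endocrine genes had 2 of 15 (13.3%, matched 11.7%), LEPR, the leptin receptor, with 2 and GHRL, the ghrelin precursor, with 1. Exocrine pancreas genes had 1 of 24 (4.17%, matched 5.02%), the mucin gene MUC1 with 8. Interferon response genes had 1 of 18 (5.56%, matched 11.9%), MX1 with 1. Proliferation genes had 2 of 19 (10.5%, matched 18.0%), among them BUB1, a mitotic checkpoint kinase, with 1. Stromal, endothelial and immune genes had 0 of 16 (matched 6.42%, upper 95% limit 20.6%) and housekeeping genes 0 of 20 (matched 10.1%, upper 95% limit 16.8%). With matching on genomic span and without matching, the random share was 12.3% and 12.5% for exocrine genes and 15.3% and 12.4% for stromal, endothelial and immune genes. For other islet endocrine genes it was 9.63% and 12.5%, and for proliferation genes 15.8% and 12.5%. Requiring at least 3 models, other islet endocrine genes had 0 of 15 against 3.00% in random lists. Exocrine genes then had 1 of 24 against 1.11%. Each of the 13 lists lay within the central 95% of its matched random lists, under the main matching, and the adjusted empirical p was 1 for each. Under that matching, the smallest unadjusted empirical p was 0.181, for housekeeping genes. Their matching counted haplotype copies of RPS18 and TUBB as extra reference transcripts. On chromosomes 1 to 22, X and Y alone, their matched share was 7.24% and the empirical p 0.345. Without matching, the unadjusted empirical p was 0.032 for exocytosis and excitability genes and 0.0368 for diabetes loci. The adjusted p was 0.239 for each of the 2. Lists of this size leave wide intervals. The simulated lists held 20 genes, each with more than 1 reference transcript. With the odds raised by a factor of 3, 38.5% of them had an unadjusted p under 0.05. Every real list also held genes with a single RefSeq transcript, 21 of 24 in the exocrine list, so recovery there may be lower.

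**Figure D2:**
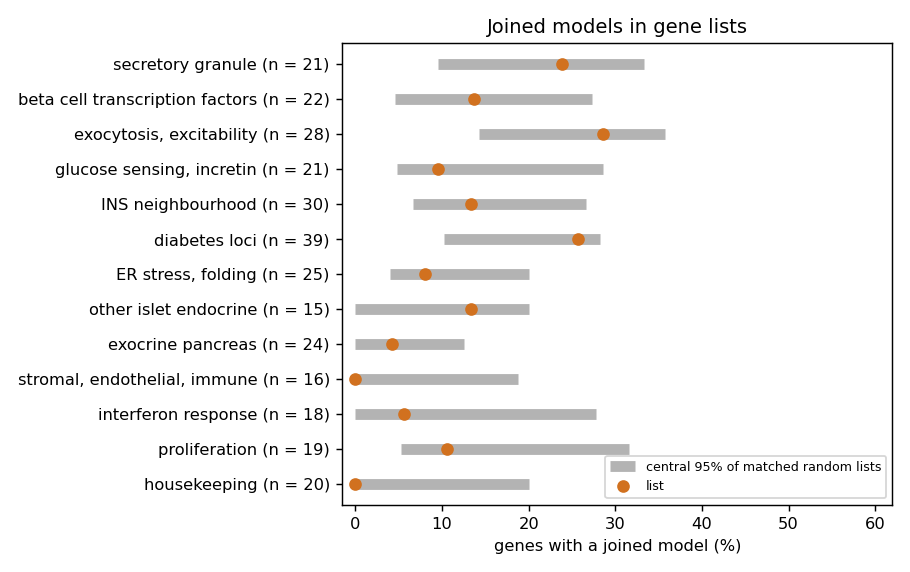
Percent of genes with a joined model (horizontal axis) in each of the 13 gene lists; orange points are the lists with n genes tested, and grey bars are the central 95% of 10000 random lists matched on transcript and exon number. Each point lies within its bar, from 0% for housekeeping genes to 28.6% for exocytosis and excitability genes.

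In the whole file, 2677 of 21516 multi-exon gene names (12.4%, 95% interval 12.0 to 12.9%) had a joined model. The genes with the most were NRM with 42, TAPBP with 25, LST1 with 24, TSNAX-DISC1 with 23, AGER, BAG6, MSH5-SAPCD1 and PPT2-EGFL8 with 21 each, DDR1 with 20 and NDRG2 with 19, the last tied with UTY on chromosome Y. All of these but TSNAX-DISC1, NDRG2 and UTY lie in the major histocompatibility region of chromosome 6, which hg19 carries in several haplotype copies. Counted on chromosomes 1 to 22, X and Y alone, NRM had 6, TAPBP had 5 and LST1 had 3, while TSNAX-DISC1 kept 23 and NDRG2 kept 19.

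The joined models introduced almost no new splice junction. Of the 5237, 5228 used annotated introns alone, and 5217 began and ended at the outer ends of reference transcripts. Both held for 5208 (99.4%, 95% interval 99.2 to 99.6%). A chain of 4491 models (85.8%) was made of 2 runs of reference introns, 379 of 3 and 50 of 4 or more. In 308 models the chain was a single run from 1 reference transcript but identical to no whole reference chain. The 9 other models, at AQP1, ECM1, EGR2, FAM96B, LOC101927482, NBPF14, PSRC1 and, with 2, LINC01128, held 8 distinct introns outside the reference, of which 5 were GT-AG and 0 were in GENCODE. These 8 genes were chosen after their values were seen. The NBPF14 intron spanned 762191 bases of chromosome 1 and had no GT-AG ends. NBPF14 belongs to a family of near-identical copies.

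The presence of a joined model rose with the number of RefSeq transcripts at the locus. It was 0 of 16208 loci with 1 transcript (upper 95% limit 0.0228%), 5.93% of 4282 loci with 2, 33.7% of 2351 loci with 3 and 80% of 120 loci with over 10. A chain that combines introns of different reference transcripts cannot arise at a locus with 1. For such chains the 0 was fixed in advance, and more transcripts allow more combinations.

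**Figure D3:**
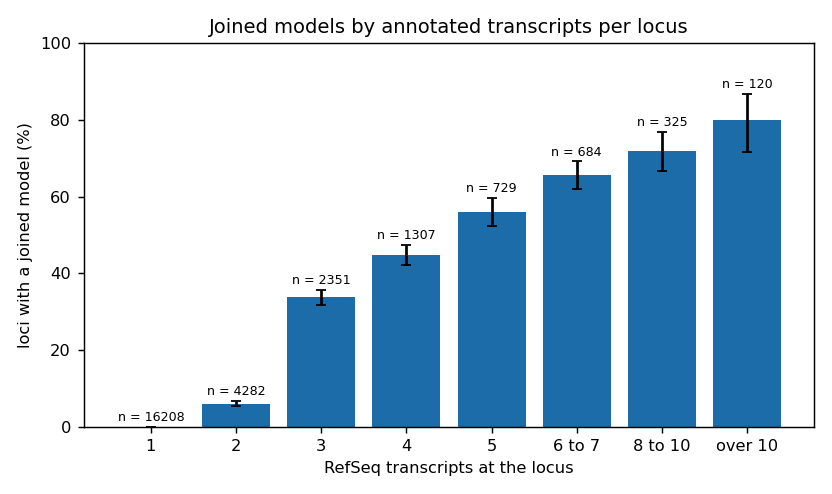
Percent of loci with a joined model (vertical axis, from 0) by the number of RefSeq transcripts at the locus (horizontal axis); error bars are exact 95% binomial intervals and n is the number of loci. The share is 0% at 1 transcript, 33.7% at 3 and 80% above 10. Chains that combine introns of different transcripts cannot occur at 1 transcript.

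The joined models had a median of 12 exons and 3171 spliced bases, against 7 exons and 2430 bases for reference transcripts. The reference medians were taken over all loci, including the 16208 with 1 transcript, where no joined model occurred. They do not compare transcripts of the same loci. Of the 4940 joined models on chromosomes 1 to 22, X and Y, 337 (6.82%) had a chain present in GENCODE, against 88.0% of 43307 multi-exon reference transcripts. Joined models were selected as chains absent from RefSeq, and the comparison set was RefSeq itself. The gap is therefore no measure of the support for the joined models. In 4314 joined models with a protein-coding nearest reference, the longest frame was shorter than that of the reference in 74.2%, equal in 11.3% and longer in 14.6%, with a median of 92.1% of its length. An early stop occurred in 434 (10.1%) of them and in 39 (1.65%) of the 2359 nearest references. These values come from genome sequence, and models of 1 gene are not independent, so no test was made. Each model was set against the reference tagged as nearest alone, and other RefSeq transcripts of the gene were not compared with it. That tag need not name the closest transcript. All joined models at MUC1 carried the same tag, as did those from different start site groups at ANK1 and at CACNB2. The nearest references were limited to protein-coding accessions, while the joined models passed no such selection. The shares of frames and early stops therefore need not compare a model with its closest transcript. How far the choice of reference shapes them is unknown.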

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

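No paired analysis was possible because the merged assembly carries no value per library, so the planned expression fits, their replicate block, the pseudocount and filter alternatives and the fits without single replicates were not run. The random-window comparison around INS and its 0.5 Mb version gave no value, since no intergenic model exists. The counts of models kept within 1.5 times under both restrictions, to chromosomes 1 to 22, X and Y and to models of at least 200 bases. The share of genes with a joined model, 12.4%, became 13.5% when limited to genes with a reference transcript of 3 or more exons, and stayed within its interval under the other 4 settings. Adding class o moved nothing, because the file holds no such model. Of 78 list results under alternatives, 6 changed sign, none of them past the threshold: without matching, beta cell transcription factors lay 1.16 and the INS neighbourhood 0.854 percentage points above random lists; with matching on genomic span, the INS neighbourhood lay 2.65 above; requiring at least 3 models, exocytosis genes lay at -0.42, other islet endocrine genes at -3.00 and exocrine genes at 3.06. The cause was not tested. With their sign kept, 7 lists moved by over 1.5 times with matching on genomic span, 9 without matching, 7 with at least 3 models, 1 on the main chromosomes and 4 with exact matching. With matching on span and without matching in turn, the difference from random lists went from 3.27 points to 9.75 and 11.4 for granule genes, from 2.91 to 9.18 and 16.1 for exocytosis genes, from -2.57 to -6.18 and -4.54 for ER stress genes, from -0.855 to -8.15 and -8.32 for exocrine genes and from -6.42 to -15.3 and -12.4 for stromal, endothelial and immune genes. Without matching, genes at diabetes loci went from 7.17 to 13.2 and proliferation genes from -7.52 to -1.98. The smallest adjusted p over the 78 was 0.239. The restriction to the main chromosomes was planned for the counts of models; for the share of genes and the lists it was chosen after seeing the data, as was the exact matching on transcript number. Without any read count, depth limits every statement on expression.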

Other observations

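The tests of splice evidence and of read-through names were chosen after the pattern was seen; those of gene families, whole loci and haplotype copies were written before their results. Read-through genes stood out among gene names with joined models. Of 121 names that fuse the symbols of 2 genes, such as INS-IGF2, TSNAX-DISC1 and MSH5-SAPCD1, 61 (50.4%) had a joined model, against 7.73% in lists matched on the name's own transcripts and exons (permutation p = 0.0002, the smallest that 10000 lists can give). Of the 121 names, 82 had 1 reference transcript of their own. Loci with 1 transcript had no joined model, so matching on the name sets a low baseline. The p does not measure an excess over loci of equal size. A candidate explanation is that the loci of read-through genes hold more annotated transcripts to join, since the genes on either side share the locus. Matched on the whole locus, 97 of 144 read-through loci (67.4%) had a joined model, inside the 58.3 to 71.5% of random loci, and their median was 6 reference transcripts against 1 elsewhere. Some of the 144 are haplotype copies of 1 gene and are not independent. On chromosomes 1 to 22, X and Y alone, a restriction added after seeing the data, 73 of 120 loci (60.8%) had one, inside 54.2 to 69.2%. An excess was thus not detected at the level of the locus, and the INS-IGF2 models may be a case of the same kind.

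What the joined models rest on bears on any use of this assembly. One hypothesis is that they were put together from the RefSeq transcripts with no new splice evidence. Of the models, 99.6% began and ended at reference ends, but this was seen before the test was chosen and decides nothing. The alternative, that expression in the beta cell libraries set which genes gained a joined model, could not be tested without expression values. Families chosen by symbol were contrasted instead, with shares weighted to match transcript and exon number. Families used by nearly every cell (such as ribosomal, proteasome and splicing proteins) had a joined model in 59 of 349 genes, a weighted share of 18.1%. Families of immune, germ and muscle cells had a joined model in 84 of 342 genes, a weighted share of 22.8%. The weighted difference was -4.74 percentage points (95% interval -9.60 to 0.0422, permutation p = 0.0834), so a larger share in broadly expressed families was not detected. Expression of either set in these libraries is unknown, so the contrast does not decide the alternative. Reads confined to annotated junctions in a reference-guided assembly may give similar chains, so whether reads contributed cannot be told apart here without the alignments. No biological explanation was tested, and the contrast of families is indirect.

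Joined models also recurred on the 7 haplotype sequences of chromosome 6, which held 290 of them. On them, 179 gene copies had the same number of reference transcripts and the same intron lengths as on chromosome 6. A gene can enter once per haplotype sequence, so the copies are not independent. Of the 179, 178 had the same number of joined models as on chromosome 6. So did 34 of the 35 with a joined model on either copy (97.1%). This is consistent with the reference transcripts of each copy fixing the models, although reads that align equally to all copies could give the same result.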
